A study of Mus musculus with 4 samples.

How the data were processed

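The deposited intensity values had been processed by the authors with RMA, a method made up of background correction, quantile normalization and probe summary, per the series design text and the submitters' processing notes, whose software and version are not given in the sources used here. The deposited values lay on a linear scale, although a log2 scale had been assumed when the comparisons were set out, so log2 was taken here before any difference was calculated. Per the labels' protocols, RNA was extracted with Trizol, equal amounts from 5 mice were pooled for each array, and whole-transcript sense targets were made without reduction of ribosomal RNA. All 4 arrays were used, grouped by their titles into pregnant or non-pregnant and MCMV or mock, and the number of unused value columns was 0.

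Of 35557 probe sets, 21789 were assigned to 1 gene by the platform annotation. Another 1621 were assigned to several genes and 12147 were not listed, and neither kind was given a gene name. Gene symbols were updated through a RefSeq gene table, which matched 21698 probe sets and left 19938 genes, and no coordinates were used because the files name no genome build. A gene with several probe sets was represented by the one with the highest mean. Genes were treated as expressed when the highest of the 4 values reached the median of all named values (intensity 8.03, log2 3.01). A gene dim in the other pools thus entered through the pool where it was high, which favours a difference toward that pool. Lhcgr, Prlr and Cyp19a1, which had no probe set of their own in the annotation, and Isg15 and H2-K1, which shared theirs with other genes, were not analysed here.

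Single arrays were compared as differences of log2 values, counted at 2-fold in either direction and without p-values. The effects of infection and of pregnancy, each averaged over the other factor, were tested with limma (version 3.58.1 in R 4.3.3) in an additive model of the 4 arrays, with empirical Bayes moderation and Benjamini-Hochberg adjustment over the expressed genes. The residual degree of freedom was 1 and the prior degrees of freedom 6.04. The residual holds real differences between the infection responses as well as noise. The noise SD was taken from the robust spread of the difference of the responses, a definition chosen after the data had been seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

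The 27 gene lists were written from background knowledge before the data were examined. The median difference of each list with at least 5 expressed members was set against 10000 random lists of the same size drawn from 10 bins of mean expression, and a list was called outside when it left the central 95% of them. Genes in a list are co-regulated, which random lists do not copy. Genes named in the text were the 8 largest in each direction of each comparison, up to 4 largest members of a list, and a set of genes fixed in advance. Predicted genes, Riken clones, receptors of smell, antigen receptor segments and small RNAs were passed over, and exceptions are said to have been named after their values were seen.

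The alternatives chosen in advance were array median centring, loess removal of intensity trends (span 0.3), no expression filter, a filter on the mean, the mean of all probe sets of a gene, 16 added to each intensity, 1.5-fold in place of 2-fold, an intensity trend in limma, unmatched random lists and lists without their largest member. The limma and list steps were tested on simulated data. With 200 of 10756 genes changed, 5 of 10556 unchanged genes were called. Of 100 unshifted lists 2 were outside, and of 100 lists shifted by 0.5 all 100 were.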

Results

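Gene expression was measured in mouse ovaries with 4 Affymetrix Mouse Gene 1.0 ST arrays, which report the signal of whole transcripts. The mice were BALB/c females, either pregnant or not, and either infected with murine cytomegalovirus (MCMV), a natural herpesvirus of mice, or mock infected. There was 1 array for each of the 4 groups, and each array was hybridised with RNA combined in equal amounts from the ovaries of 5 mice. Virus was injected intravenously at a dose taken here as 200000 plaque-forming units, from a notation in the labels that can also be read as a larger dose. Pregnant mice were infected at day 9.5 after conception, and RNA was taken 5 days later, at day 14.5. The non-pregnant mice had received pregnant mare's serum gonadotropin and then human chorionic gonadotropin, hormones that drive follicle growth and ovulation, and the sources used here do not date this treatment relative to infection. Pregnancy was therefore compared with gonadotropin-primed ovaries.

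The median intensity of a probe set was between 5.56 and 5.85 on the 4 arrays, and the log2 values of any pair of arrays correlated across probe sets with a Pearson r between 0.968 and 0.977. Of 19938 named genes, 10756 reached an intensity of 8.03 on at least 1 array and were treated as expressed. With 1 array per group there was no replicate error, the number of arrays limits the precision, and differences between single arrays are given as sizes without p-values. As a yardstick, the robust SD of a difference between arrays, estimated from how far genes departed from an additive pattern, was 0.27 on the log2 scale. Differences are infected minus mock, or pregnant minus non-pregnant, on the log2 scale unless a fold is given. A difference whose lower value lay under the expression limit rests on a background-level value, so its size and rank are imprecise.

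The first comparison addressed what MCMV infection did to ovarian gene expression during pregnancy. The gene with the largest difference was Akr1c18, which encodes the ovarian enzyme that converts progesterone to an inactive metabolite. Its intensity was 1970.4 in the infected pregnant pool and 11.6 in the mock-infected pregnant pool, a 169.7-fold difference. Next came Prap1, a secreted epithelial protein gene (difference 6.74), Lcn2, which encodes the iron-sequestering protein lipocalin 2 (5.39), and Sprr2f, an epithelial gene of the small proline-rich family (4.97). For Prap1, Sprr2f, Iigp1, Cxcl10 and Zbp1 the mock value was under the expression limit (intensities 3.92, 2.16, 6.88, 6.17 and 4.31), so these sizes are imprecise, while Lcn2 was at 813 against 19.4. The interferon-induced genes Iigp1 (4.87), Cxcl10 (4.56), Gbp3 (4.35) and Zbp1 (4.23) completed the 8 largest. They encode an immunity-related GTPase, a chemokine for activated lymphocytes, a guanylate-binding protein and a sensor of viral nucleic acid.

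Interferon-stimulated genes, which restrict viral replication, were higher in the infected pregnant pool for 26 of 26 expressed members, all by at least 2-fold. Their median difference was 2.35, above all 10000 random lists of matched expression, and Irf7 (3.91), Ifit3 (3.72) and Ifit2 (3.33) were among the largest. Of 16 expressed interferon-gamma-inducible GTPases and chemokines, 14 were at least 2-fold higher, with a median of 3.19, including Cxcl9 (3.51) and Gbp4 (3.81). Genes of MHC class I antigen presentation had a median difference of 1.79, with 8 of 13 at least 2-fold higher. The largest were H2-Q4, a non-classical class I gene (3.36), the peptide transporter gene Tap1 (3.18), the immunoproteasome gene Psmb8 (2.95) and B2m, the class I light chain (2.19). Class II genes had a median of 1.98, with 4 of 6 at least 2-fold higher, among them the invariant chain gene Cd74 (2.77) and H2-Eb1 (2.30).

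Transcripts of immune cells were also higher. Macrophage and monocyte markers had a median difference of 1.75, and 11 of 14 were at least 2-fold higher, with Mpeg1 (2.86), the Fc receptor gene Fcgr4 (2.81) and the integrin gene Itgam (2.56) in front. Only 6 of 20 markers of natural killer and cytotoxic lymphocytes were expressed, and 5 of these were at least 2-fold higher. The cytotoxic granule gene Gzmb differed by 3.82, Ccl5 by 2.03 and Gzma by 1.97. Ifng, Cd8a and Ncr1, markers of activated lymphocytes, cytotoxic T cells and natural killer cells, lay under the expression limit in all 4 pools. Of the 13 T cell markers with a probe set of their own only Thy1 was expressed (0.42), and of the 9 such B cell markers none was. Of 20 inflammatory cytokine and chemokine genes only 7 were expressed. They had a median of 1.36 with 6 of 7 at least 2-fold higher, led by Ccl3 (5.66-fold) and Ccl12 (2.13). All but Cxcl16 were under the expression limit in both mock pools, as were Gzmb and Gzma. The same held for at least Fcgr4, Fcgr1, Cd14 and Adgre1 among the macrophage and monocyte markers. These genes counted as expressed through the infected pools, so the filter favoured a rise. Their part in the counts is no independent support for it. For acute phase and complement genes the median was 1.51 with 7 of 11 at least 2-fold higher, and after Lcn2 the largest were Cfb (2.78), C4b (2.52) and Saa3 (2.06).

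Genes tied to the corpus luteum, the progesterone-producing gland that maintains pregnancy in mice, mostly showed smaller differences, apart from several luteolysis-associated genes such as Akr1c18. No member of the progesterone synthesis and sterol uptake list differed by 2-fold, and the list median was -0.28, at percentile 0.06 of the random lists. Star, which delivers cholesterol to the mitochondrion, differed by -0.48, the side-chain cleavage enzyme gene Cyp11a1 by -0.53, the lipoprotein receptor gene Scarb1 by -0.64 and Hsd3b1 by -0.21. The theca enzyme gene Cyp17a1 differed by -0.69. Tspo, a mitochondrial membrane protein gene of the same list, was higher (0.98). Cholesterol biosynthesis genes had a median of -0.38 with 15 of 18 below 0, led by Hmgcs1 (-0.99) and Insig1 (-0.99). Luteal hormone receptors and prolactin-responsive genes had a median of -0.30, with A2m, a protease inhibitor gene, at -1.41 and Ptgfr, the receptor for the luteolytic prostaglandin, at -0.45. Of the 9 expressed members 7 were below 0, while the oestrogen receptor gene Esr1 was at 0.17. The receptor genes Lhcgr and Prlr of this list were not analysed in any comparison, so its medians say nothing about them. Luteolysis-associated genes had a median of 0.68, above the central 95% of random lists, and 4 of 13 were at least 2-fold higher. These were Akr1c18, Ptgs2, the inducible prostaglandin synthase gene (2.91), the protease inhibitor gene Timp1 (2.65) and the chemokine gene Ccl2 (1.67). Ccl2 is also in the cytokine list and counted as expressed through the infected pools. Ptgs2 is also in the list of ovulation and cumulus genes, so these lists are not separate evidence.

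**Figure D1:**
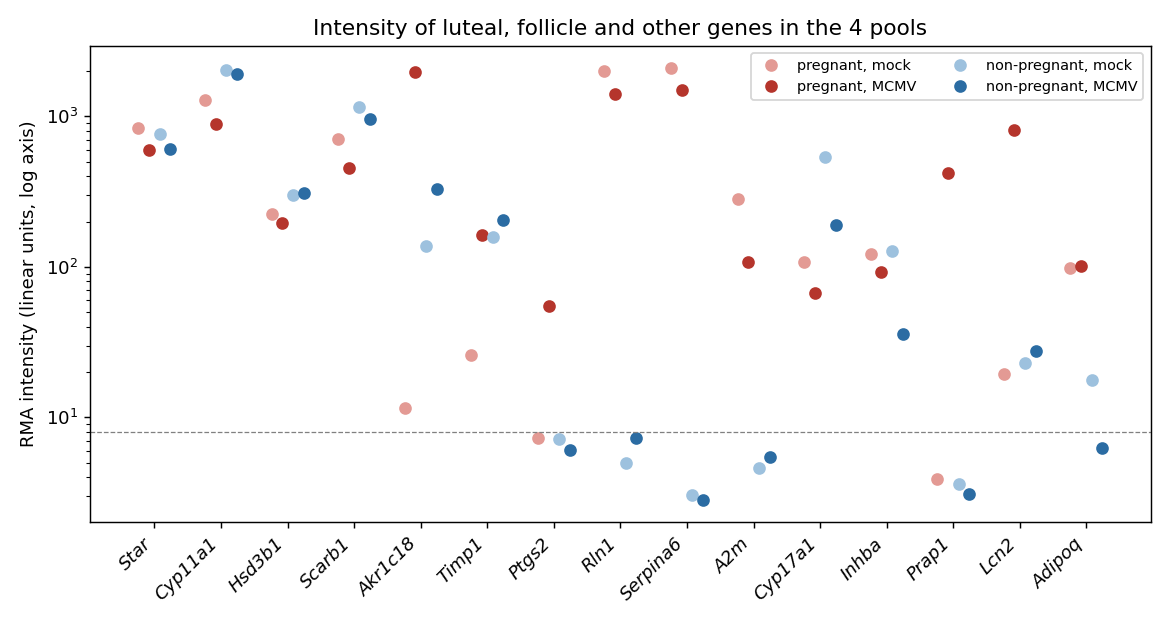
RMA intensity (linear units on a log axis) of 15 genes in each of the 4 pools, 1 point per array, with the expression limit of 8.03 as a dashed line. Akr1c18 lies at 11.6 in the pregnant mock pool and at 1970.4 in the infected pregnant pool, while Star lies between 597 and 832 in all 4.

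Other tissue compartments also differed in the pregnant pair. Surface epithelium and oviduct markers had a median difference of 0.94, with 6 of 12 at least 2-fold higher, including the keratin genes Krt7 (1.95), Krt8 (1.35) and Krt19 (1.05). Ovulation and cumulus genes had a median of 1.07, with Ptgs2, Tnfaip6, a hyaluronan-binding protein gene (2.59), and the protease gene Adamts1 (1.35) higher and the growth factor gene Ereg lower (-1.16). Ereg reached the expression limit in the pregnant mock pool alone (intensity 8.18), so the filter favoured its fall and its size is imprecise. Stromal and extracellular matrix genes had a median of 0.29, above the central 95% of random lists. Granulosa and follicle markers had a median of -0.42, below all random lists, with 10 of 12 members below 0, among them Hsd17b1 (-0.67), Inha (-0.60) and Fst (-0.60). Oocyte markers had a median of -0.19, at percentile 1.31, and this position was lost when the largest member, Bmp15 (-0.63), was left out. The lists of endothelial (-0.01), cell cycle (0.17), stress response (0.08), adipose (0.13) and housekeeping genes (0.13) lay within the central 95% of random lists.

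In all, 336 genes were at least 2-fold higher and 35 at least 2-fold lower in the infected pregnant pool. The largest negative difference was that of Alas2, the erythroid enzyme of haem synthesis and the expressed one of only 2 erythroid markers analysed here (-2.41). It was followed by the retinol dehydrogenase gene Rdh1 (-1.99), the protease inhibitor gene Mug1 (-1.72), Cst12 (-1.65), Bhmt, an enzyme of methionine metabolism (-1.65, smaller with the mean of its probe sets), the endothelial scavenger receptor gene Stab2 (-1.58), Dcpp1 (-1.51) and Scd1, the fatty acid desaturase gene (-1.43). Adding 16 to every intensity before taking logs reduced both counts by more than 1.5 times, as given in the closing part. This step shrinks differences near background most but also those of brighter genes, and the share of dim genes in the counts was not determined. Centring each array on its median gave 297 higher and 63 lower, a higher share of 82.5% against 90.6%.

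The second comparison addressed the same question in non-pregnant, gonadotropin-primed mice. Here the 8 largest positive differences were almost all interferon-induced genes. Iigp1 was 51.6-fold higher (5.69), Cxcl10 38.2-fold (5.26) and the antiviral gene Ifit3 33.7-fold (5.08). Zbp1 (4.54), Gbp4 (4.45), Ifit1 (4.19), Irf7 (4.16) and Ifit3b (4.09) followed. Of these 8 genes, all but Gbp4 and Irf7 had mock intensities under the expression limit, so their sizes are imprecise. All 26 expressed interferon-stimulated genes were at least 2-fold higher, with a median of 3.12, and 15 of 16 interferon-gamma-inducible GTPases and chemokines were, with a median of 3.50.

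Antigen presentation genes were higher as well, with medians of 1.86 for class I and 2.36 for class II, and H2-Q4 (3.89), Tap1 (3.57), Cd74 (2.52) and H2-Ab1 (2.47) among the largest. Gzmb differed by 3.32, Gzma by 1.49 and Ccl5 by 1.20, and 3 of the 6 expressed natural killer and cytotoxic markers were at least 2-fold higher. Macrophage and monocyte markers had a median of 0.65, with 4 of 14 at least 2-fold higher, namely Fcgr4 (3.39), Mpeg1 (3.10), Fcgr1 (1.65) and Itgam (1.23). For Gzmb, Gzma, Fcgr4 and Fcgr1, under the expression limit in both mock pools, the filter favoured a rise. The cytokine and chemokine list, limited by the filter as above, had a median of 1.20, with Ccl3 (1.82) and Ccl7 (1.52) in front. For the acute phase and complement list the median was 0.71, with C4b (3.37) and Cfb (2.53) in front. Thy1 differed by 0.45.

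Progesterone synthesis genes did not stand apart from random lists (median -0.13, percentile 48.2). Star differed by -0.32, Cyp11a1 by -0.09 and Hsd3b1 by 0.04, while Akr1c18 was 2.41-fold higher. Cyp17a1, the androgen-producing enzyme of theca cells, differed by -1.49. Granulosa and follicle markers had a median of -0.51, with 12 of 12 below 0, and the inhibin and activin subunit genes Inhba (-1.82) and Inhbb (-1.34) and the oestrogen-forming enzyme gene Hsd17b1 (-1.02) at least 2-fold lower. Amh, a marker of small growing follicles, differed by -0.06 and the oocyte gene Gdf9 by 0.13. Cholesterol biosynthesis genes had a median of -0.43, with 17 of 18 below 0, and endothelial markers a median of -0.31. Adipose markers had a median of -1.40, below all random lists, with Adipoq, the adiponectin gene (-1.49), the lipid droplet gene Cidec (-1.49) and the fatty acid-binding protein gene Fabp4 (-1.40) at least 2-fold lower. The lists of oocyte (-0.04), epithelial (-0.05), ovulation (0.04), luteolysis-associated (0.06), luteal receptor (0.02), stromal (-0.23), cell cycle (-0.18), stress response (-0.20) and housekeeping genes (-0.09) lay within the central 95% of random lists. The stromal list lay below that range after loess correction, and the luteolysis-associated list above it without the expression filter (median 0.15).

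In the non-pregnant pair, 185 genes were at least 2-fold higher and 48 at least 2-fold lower. The lowest were Scd1 (-2.33) and Car3, a carbonic anhydrase gene of fat and muscle (-2.22), followed by the proteoglycan gene Spock2 (-1.87), Grem1, a secreted antagonist of bone morphogenetic proteins (-1.84), Inhba, the lipoxygenase gene Alox15 (-1.80), the proton pump gene Atp12a (-1.66) and the pericyte gene Rgs5 (-1.56). Both counts were again smaller with 16 added to every intensity.

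The infection responses of the 2 reproductive states were then set against each other. Across the 10756 expressed genes the infection differences in pregnant and non-pregnant mice correlated with a Pearson r of 0.46 and a Spearman rho of 0.09, where genes are not independent replicates. Of the 336 and 185 genes at least 2-fold higher, 151 were higher in both states, against 5.78 for independent lists, and the 2 differences share no array. Dcpp1, Scd1 and the olfactory receptor gene Olfr1251, the last named after its values were seen, were at least 2-fold lower in both states, against 0.156 for independent lists.

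**Figure D2:**
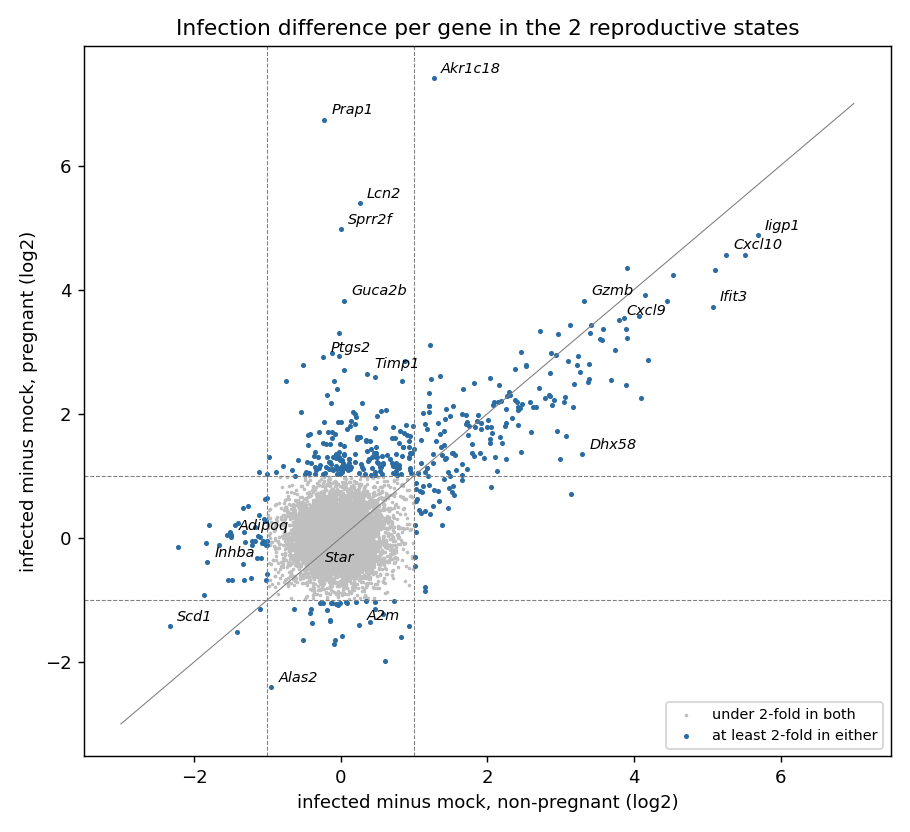
Log2 infection difference (infected minus mock) of each of 10756 expressed genes in non-pregnant mice (x axis) and pregnant mice (y axis), with dashed lines at 2-fold and the line of equal difference. Iigp1 and Cxcl10 lie far out in both states, while Prap1, Lcn2 and Sprr2f lie near 0 in non-pregnant mice, where Prap1 and Sprr2f were under the expression limit, and above 4 in pregnant mice.

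An additive limma model, with infection and reproductive state as its terms, tested the infection effect averaged over both states. At an adjusted p under 0.05, 164 genes rose and 3 fell with infection, where 13 fell with an intensity trend in the model and 1 without the expression filter. Zbp1 rose by 4.39 (SE 0.19, adjusted p = 0.000228 by limma), Cxcl10 by 4.91 (SE 0.22, adjusted p = 0.000228 by limma) and Gzmb by 3.57 (SE 0.20, adjusted p = 0.000266 by limma), each higher in 2 of 2 infected pools. Scd1 fell by 1.88 (SE 0.25, adjusted p = 0.0113 by limma), Dcpp1 fell by 1.47 (adjusted p = 0.00816 by limma) and Olfr1251 fell by 1.13 (adjusted p = 0.0299 by limma). Among the lists, 26 of 26 interferon-stimulated genes rose, as did 14 of 16 interferon-gamma-inducible genes, 9 of 13 class I genes, 4 of 6 class II genes, 4 of 6 natural killer and cytotoxic markers, 5 of 14 macrophage markers, 4 of 7 cytokine genes and 5 of 11 acute phase and complement genes. Adjusted over the list alone these counts were 26, 14, 12, 6, 5, 9, 6 and 7. Gzmb, Gzma, all cytokine genes but Cxcl16 and several macrophage markers entered this test through the infected pools. The counts of these 3 lists are therefore no independent support for a rise. No member of the progesterone synthesis, cholesterol biosynthesis, granulosa or epithelial lists passed over all genes. Adjusted over the list alone, 6 of 12 granulosa and follicle markers fell, as did 1 of 18 cholesterol biosynthesis genes. Akr1c18, with an averaged difference of 4.34 (SE 1.17), had an adjusted p of 0.269 by limma, since its differences in the 2 states were far apart.

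The spread in this model is the departure from additivity, with 1 residual degree of freedom, and not an error between mice. On simulated data with this design, 91 of 100 genes changed by 2 on the log2 scale were called and 4 of 100 changed by 1, so a gene that did not pass may still have differed by 2-fold.

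**Figure D3:**
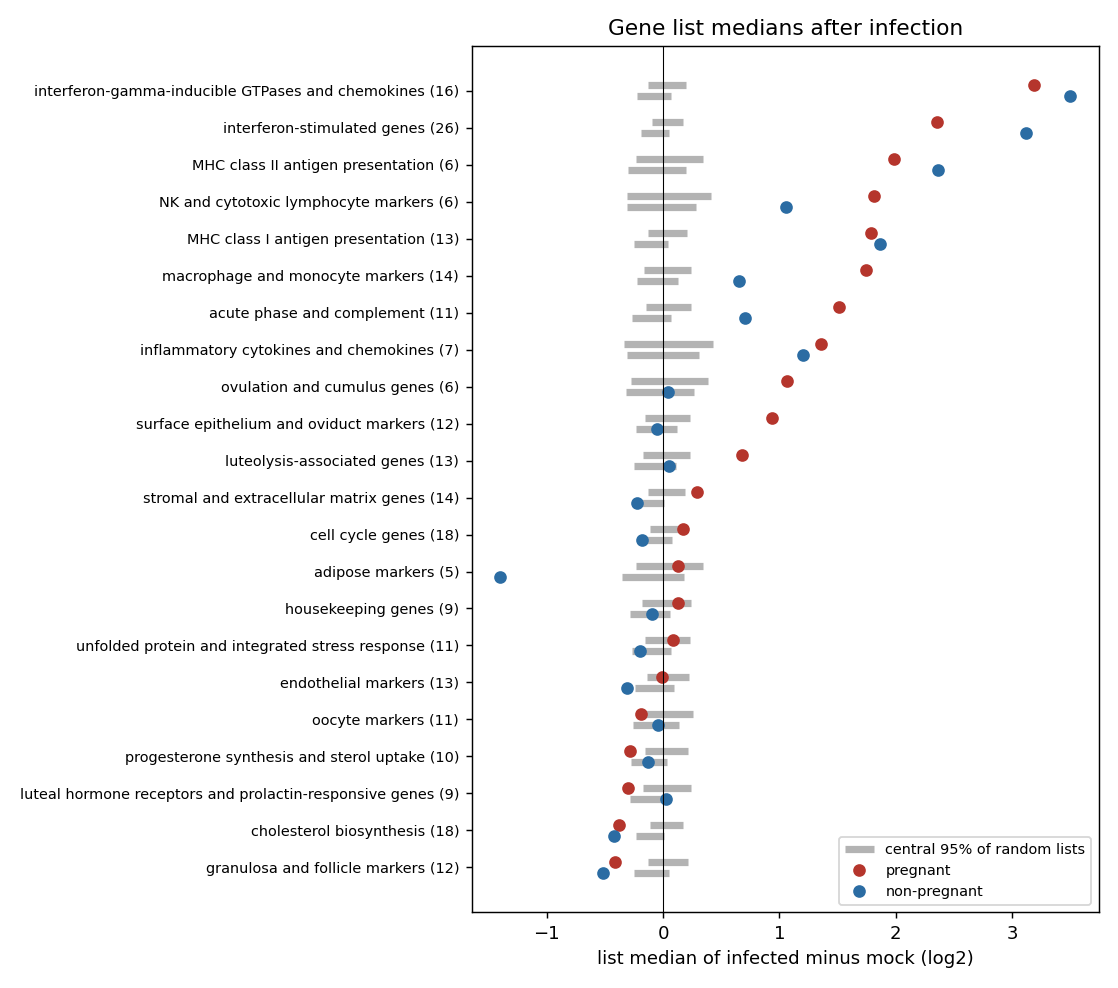
Median log2 infection difference of each gene list (number of expressed members in parentheses) in pregnant (red) and non-pregnant (blue) mice, with grey bars for the central 95% of medians of random lists. The interferon and antigen presentation lists lie far to the right in both states, and the adipose list lies at -1.40 in non-pregnant mice and at 0.13 in pregnant mice.

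The difference between the responses, pregnant minus non-pregnant, was largest for Prap1 (6.97), Akr1c18 (6.14), Lcn2 (5.13), Sprr2f (4.97), the guanylate cyclase ligand gene Guca2b (3.77), the immunoglobulin receptor gene Pigr (3.32), the membrane trafficking gene Mal2 (3.30) and Usp17ld (3.28). In both non-pregnant pools Prap1, Sprr2f, Guca2b, Pigr and Mal2 were under the expression limit. None of these genes rose past the limit with infection there, but their rank and any smaller response cannot be read from the values. Akr1c18 was above the limit in all 4 pools, as was Lcn2. Among the most negative were Rdh1 (-2.60), BC023105 (-2.43), Galntl5 (-2.35), the RNA sensor gene Dhx58 (-1.94), Heatr4 (-1.93), Ifit3b (-1.84), Dnah7c (-1.80) and Ggct (-1.75). Rdh1, Galntl5 and Dnah7c were under the expression limit in both non-pregnant pools, and BC023105 was in both pregnant pools. For these genes the response in that state and the rank cannot be read from the values. Interferon-stimulated genes had a median of -0.57, below all random lists, with 24 of 26 members below 0, and interferon-gamma-inducible genes a median of -0.53. Class I genes had a median of -0.28. Macrophage and monocyte markers had a median of 0.96 with 12 of 14 above 0. They included Cd68, a lysosomal protein gene (1.47), Cd14, the lipopolysaccharide co-receptor gene (1.37), Itgam (1.34) and the complement gene C1qc (1.31). Cd14 and Adgre1 reached the expression limit in the infected pregnant pool alone, so the filter favoured a difference above 0 for them. Adipose (1.53), ovulation (1.02), epithelial (0.85), luteolysis-associated (0.62) and cell cycle genes (0.46) also lay above the central 95% of random lists. Natural killer and cytotoxic markers did so as well (0.57), but not once the largest member was left out or without the expression filter. Luteal receptor and prolactin-responsive genes (-0.28) and progesterone synthesis genes (-0.15, percentile 0.63) lay below the central 95%, the latter not against random lists without matching.

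By size, 314 genes had a difference of responses of at least 1 and 128 of at most -1, a higher share of 71.0%, but after centring each array on its median the counts were 208 and 225, a higher share of 48.0%. The median over all genes was 0.11 before centring and -0.02 after it, and with 1 array per group no difference of responses was tested.

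The last comparisons addressed pregnancy itself, against gonadotropin-primed ovaries. In the mock-infected mice Serpina6, which encodes the corticosteroid- and progesterone-binding globulin, was 691.6-fold higher in the pregnant pool, with an intensity of 2109.3 against 3.05. Rln1, the gene of the pregnancy hormone relaxin, was 403.5-fold higher. Both non-pregnant values were under the expression limit, as were those of A2m, Ces2a and Mug1 among the next genes. A2m (5.95), the potassium channel gene Kcnj16 (5.03), the carboxylesterase gene Ces2a (4.69), the glycoprotein hormone gene Stc1 (4.29), Mug1 (4.14) and Ggct, an enzyme of glutathione turnover (15.9-fold), followed. Lower in the pregnant pool were Cyp11b1, a steroid hydroxylase gene (-5.40), Akr1c18 (-3.56), Lrrn1 (-3.53), the fatty acid desaturase gene Fads2 (-3.08), Xpnpep2 (-2.95), Timp1 (-2.62), Hao2 (-2.46) and Cemip (-2.42).

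Cholesterol biosynthesis genes had a median of -0.96 in the mock-infected mice, and 9 of 18 were at least 2-fold lower in the pregnant pool. They included Cyp51 (-1.94), Fdps (-1.66), Lss (-1.57) and Idi1 (-1.45). Progesterone synthesis genes had a median of -0.63, with Tspo at -1.36, the electron donor gene Fdx1 at -0.92, Cyp11a1 at -0.66 and Star at 0.13. Cyp17a1 differed by -2.31. Luteal receptor and prolactin-responsive genes had a median of 0.27, with A2m, the steroid reductase gene Hsd17b7 (2.29) and the oestrogen receptor gene Esr1 (2.05-fold) at least 2-fold higher. Luteolysis-associated genes had a median of -0.48 with 6 of 13 at least 2-fold lower, among them the immediate-early genes Fos (-2.13) and Egr1 (-1.96), although without the expression filter the list lay within the central 95% of random lists. Cell cycle genes had a median of -0.44, with 18 of 18 below 0. Markers of other tissues were higher in the pregnant pool, namely adipose markers (median 1.46, 4 of 5 at least 2-fold higher, Adipoq 2.49) and surface epithelium and oviduct markers (median 0.76, 3 of 12, Pax8 1.29). Acute phase and complement genes also had a median of 0.72, with Lbp (1.28) and Cfb (1.24) among the largest, while Serpina3n of the same list was lower (-1.28). Class II genes had a median of 0.30 (percentile 98.0, but within the central 95% without the largest member). Ltf, the lactoferrin gene and the only expressed neutrophil marker, differed by 2.11, and after infection by 1.06 in pregnant and -0.47 in non-pregnant mice.

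In the infected mice the median for adipose markers was 2.89 and that for epithelial markers 1.78, with 5 of 5 and 10 of 12 at least 2-fold higher in the pregnant pool. The cholesterol biosynthesis median was -1.12 and the progesterone synthesis median -0.76. Serpina6 (9.06), Rln1 (7.59), Prap1 (7.08), Sprr2f (5.14), Stc1 (5.05), Lcn2 (4.88), A2m (4.29) and Guca2b (4.14) were highest, and Cyp11b1 (-4.83), Lrrn1 (-2.99), Xpnpep2 (-2.53), Fads2 (-2.52), BC023105 (-2.38), the alcohol dehydrogenase gene Adh1 (-2.18), Hao2 (-2.12) and Mgarp (-2.09) lowest. Interferon-stimulated genes had a median of -0.67, with 25 of 26 below 0. Class I genes (-0.42) and interferon-gamma-inducible genes (-0.38) also lay below the central 95% of random lists. Macrophage and monocyte markers had a median of 0.97, with 14 of 14 above 0, which the filter favoured for Cd14 and Adgre1, expressed in this pregnant pool alone. Natural killer and cytotoxic markers (0.76), acute phase genes (0.71) and endothelial markers (0.23) lay above the central 95%. So did class II genes (0.47), stromal genes (0.27) and ovulation genes (1.13), but none of these 3 lists did so without its largest member, and ovulation genes also did not without the expression filter. Akr1c18 was higher in the pregnant pool among infected mice (2.58) and lower among mock-infected mice.

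At least 2-fold differences numbered 235 higher and 189 lower in mock-infected mice, a higher share of 55.4%, and after centring each array 305 higher and 126 lower, a higher share of 70.8%. In infected mice they numbered 421 higher and 139 lower. Both sets overlapped, with 146 genes higher in both against 9.20 for independent lists and 69 lower in both against 2.44, and the differences correlated across genes with a Pearson r of 0.56 and a Spearman rho of 0.36.

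In the additive limma model 239 genes rose and 123 fell with pregnancy, where 203 fell with an intensity trend in the model. Serpina6 rose by 9.25 (SE 0.19), Rln1 by 8.12 (SE 0.27), Stc1 by 4.67 (SE 0.23) and Ces2a by 4.28 (SE 0.24). Cyp11b1 fell by 5.11 (SE 0.21), Lrrn1 fell by 3.26 (SE 0.21) and Fads2 fell by 2.80 (SE 0.21), and the largest adjusted p among these genes was 0.00271 by limma. Among the lists, 9 of 18 cholesterol biosynthesis genes fell and 1 rose, and 4 of 5 adipose markers and 4 of 12 epithelial markers rose. Adjusted over the list alone the counts were 13, 1, 5 and 10. Cyp17a1 fell by 1.91 (SE 0.23, adjusted p = 0.0106 by limma), and Fdx1 and Tspo were the only progesterone synthesis genes to fall over all genes, with 6 falling and 1 rising when adjusted over the list alone. Without the expression filter 23 genes rose and 12 fell.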

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

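The tests of the pregnancy-high genes and of uterine tissue below were chosen only after the result was seen, as was the minimum of 1.5-fold in each direction used here to pick genes with opposite responses. The other tests of the epithelial and adipose patterns were set before their results were calculated, although some of the genes concerned, such as Cyp2e1 and Ltf, had been seen by then.

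Among named genes, 7 differed between the infected and mock pools by at least 1.5-fold in opposite directions in pregnant and non-pregnant mice, and this difference was not tested, since each group had 1 array. The pregnant minus non-pregnant difference of the responses was -2.60 for Rdh1, -2.35 for Galntl5, -1.93 for Heatr4, -1.74 for Kcnj16, 1.51 for Krt18, 2.16 for Krt19 and 3.28 for Usp17ld. The infection differences in pregnant and non-pregnant mice were -1.99 and 0.61 for Rdh1, -1.42 and 0.93 for Galntl5, and 2.53 and -0.75 for Usp17ld. Rdh1 and Galntl5 were under the expression limit in both non-pregnant pools, so neither a rise there nor an opposite direction can be read for them. For Heatr4 the lower value of each pair was under the limit, so its sizes are imprecise.

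Probe sets that no comparison used also differed after infection in both states. Of 767 expressed probe sets assigned to several genes, 33 were at least 2-fold higher and 4 at least 2-fold lower in both, against 1.88 and 0.0469 for independent lists. Of 4487 that the annotation did not list, 83 were higher and 29 lower in both, against 27.9 and 16.7.

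A set of 24 genes was at least 4-fold higher after infection in pregnant mice and less than 2-fold higher in non-pregnant mice. Their medians were 2.62 and -0.01, which this choice sets apart, and most were under the expression limit in both non-pregnant pools. Prap1, Lcn2, Pigr and Mal2 among them encode secreted or surface proteins of epithelium, but an epithelial theme of the set was not tested. The set also held Ptgs2, Timp1, Tnfaip6, Ms4a6b, Ms4a6c and Ctsc, and the tissue explanations below concern its epithelial members. More ciliated oviduct in the infected pregnant pool is argued against as the whole cause by identity genes, mostly of ciliated cells. Their 14 expressed members had a median of 0.067, and they cannot decide on oviduct tissue without cilia. Surface epithelium and oviduct markers had a median of 0.94 with 12 of 12 above 0, which goes with more epithelium. Uterine tissue cannot be told apart from a response, because only 5 developmental genes of the oviduct and uterus were expressed, several near the expression limit, with a median of 0.33. The median stayed at 2.52 or above after centring or loess, which argues against a shift of whole arrays or an intensity trend as its source. Neither step can undo the authors' normalization, and genes chosen at 4-fold could hardly lose their difference this way. The normalization itself was therefore not tested. A larger share of surface epithelium or of oviduct tissue without cilia, differences between mice, and a response to infection of epithelium present in both pregnant pools stay open as untested hypotheses.

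Adipose markers had a median infection difference of -1.40 in non-pregnant mice and were higher in both pregnant pools. Different amounts of fat around the ovaries cannot be told apart from a response of fat cells. Of 19 further adipose genes, the median was 0.84 for pregnancy in mock-infected mice, past the limit of 0.5 that goes with different amounts, but -0.45 for infection in non-pregnant mice, short of the limit of -0.5, with 17 of 19 below 0. The median stayed at -1.32 or below after centring or loess, which argues against a shift of whole arrays or an intensity trend. Neither step can undo the authors' normalization, which was not tested. A biological effect of infection on adipose transcripts stays open and was not tested.

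The 32 genes at least 4-fold higher in the pregnant than in the non-pregnant mock pool had a median infection difference of -0.49 in pregnant mice, with 24 below 0 and 7 at least 2-fold lower. A fall that arises from choosing genes on the pregnant mock pool, which both differences share, cannot be told apart from an infection effect, because neither test of it decides. Of 1000 simulated runs 0% were as low, but these gave every gene the noise of a typical gene, and 40 genes chosen on the pregnancy difference averaged over both infection states had a median of 0.042, with an SE of 0.36 too large to exclude either and with genes high in the infected pregnant pool alone, such as Prap1, among them by construction. A lower share of luteal tissue was first tested by the spread of these genes (SD 0.64 against a limit of 0.41), a test dropped because the set includes adipose genes. It was then tested by other ovarian cell types, whose medians moved apart from -0.42 for granulosa to 0.29 for stromal genes. The stromal median argues against dilution of all ovarian cells by leukocytes as the only change. Dilution together with a separate rise of stromal genes was not tested and stays open. Several granulosa markers are also made by luteal cells, so a lower luteal share alone could lower the granulosa list and this test cannot decide on it. A lower luteal share, with or without a granulosa change, stays open, and lower luteal expression was not tested.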

How the results depend on the processing

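The tests in this part were all set before the data were examined, but the noise SD used to judge named genes and the tolerance of 0.1 for the correlation were chosen only after the result was seen. No named gene past 2-fold and no list outside the range of random lists reversed direction. Of 1450 values of named genes, 1145 moved by less than the noise SD of a difference and 1278 stayed at least 2-fold. Centring shifts all genes of a comparison alike and by less than this SD, and averaging leaves genes with a single probe set unchanged. Most values under these settings therefore could not move further, and the pooled count is a weak check. With centring 345 of 363 stayed so, with loess 353 of 363, with the mean of probe sets 360 of 361, and with 16 added to each intensity 220 of 363. Of the 305 that moved further, 304 did so with 16 added, which shrinks differences of dim genes by construction, and the other was Bhmt in pregnant mice (-1.10 with the mean of its probe sets). Of 545 list medians, 528 kept their side of the central 95%, 10 came to lie inside it and 7 outside it, and the cause was not tested. With 16 added, the counts at 2-fold higher and lower were 127 and 7 for infection in pregnant mice, 101 and 8 in non-pregnant mice, 59 and 59 for pregnancy in mock-infected mice, 101 and 48 in infected mice, and 41 and 13 for the difference of the responses. After array centring 63 genes were lower with infection in pregnant mice, and the difference of the responses had 208 higher and 225 lower, through the shift of all genes by the array medians. In limma with an intensity trend, 13 genes fell with infection and 203 with pregnancy, and the cause was not tested. Without the filter 1 gene fell with infection, and 23 rose and 12 fell with pregnancy, where more genes were tested. The correlation of the infection responses was 0.36 without the filter, and the cause was not tested, while at 1.5-fold 250 genes were higher and 41 lower in both states, as a lower limit admits more genes. No paired analysis was possible because the labels carry no replicate numbers and each group had 1 array, and the additive model already holds reproductive state as its block. Leaving out an array was not possible, since it leaves no residual degree of freedom. Signal over background limits the dim genes, whose folds rest on values under 8.03.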
